A study of Physcomitrium patens with 6 samples.

How the data were processed

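The series measured RNA in protonemata, the filamentous juvenile stage, of the moss Physcomitrium patens, Gransden ecotype. Per the labels, the plants were 14 days old, after 9 days on solid and 5 days in liquid BCDAT medium, and all had been kept for 24 hours in 600 mM mannitol, a sugar alcohol used to impose osmotic stress. There were 3 wild-type libraries (WT) and 3 libraries of line 8 of ppdnmt2, a mutant of the moss homologue of DNMT2. All 6 libraries came from mannitol-treated plants, so the only comparison made was ppdnmt2 against WT under mannitol. The 3 ppdnmt2 libraries came from a single line, so effects of the mutation cannot be told apart from other differences particular to that line. RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra II RNA kit, per the labels' protocols. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

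The submitters' processing notes list bcl2fastq 2.19.0.316, FastQC 0.11.9, MultiQC 1.9, fastp 0.20.1, STAR 2.7.8a, StringTie and Cuffdiff 2.2.1, without the role or order of each. The deposited table holds 1 normalized value per locus and library for 23992 loci. Its values were taken to be FPKM (fragments normalized for transcript length and for the total of the library), because the authors' notes name Cuffdiff and StringTie and the values fit that unit; the deposited header names no unit. The genome build, the annotation and the scaling between libraries are not given in the sources used here. Of the loci, 18709 carry StringTie names for assembled loci (MSTRG) and 5283 carry RefSeq gene identifiers. Read counts were not used here, so absolute depth is unknown and no counting interval was computed. Among values under 0.2 FPKM, the commonest ratio between libraries gave the worth of 1 fragment relative to WT replicate 3. It was 0.98 and 0.97 in WT replicates 1 and 2, and 1.3, 0.97 and 1.11 in ppdnmt2 replicates 1, 2 and 3. A larger worth means fewer fragments if the values were scaled to the total of each library, which is not known here. On that reading ppdnmt2 replicate 1 was the shallowest library and its low values are the least precise.

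Loci with a mean of at least 1 FPKM over the 6 libraries were tested, which left 16817. Their values were transformed to log2(FPKM + 1) and compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, without covariates. Loci with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Fold changes on the log2(FPKM + 1) scale understate the change of loci with low values. Single values were compared with exact two-sided permutation tests in SciPy 1.17.1, whose smallest possible p for 3 against 3 libraries is 0.1. Summaries were made in Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3. On data simulated for this comparison, 200 of 16817 loci were changed, all drawn from loci with a mean above 5 FPKM. The limma step recovered 66% of the loci changed by 2-fold and 89% of those changed by 4-fold. Changes at loci with a mean of 1 to 5 FPKM were not simulated, so recovery there is unknown. Of the 163 calls of the limma step 8 were false, and it made 0 calls when no locus was changed. The simulated values were drawn independently for each locus and library. These rates may therefore not hold for the real libraries, where many loci can shift together.

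The test, the filter, the pseudocount, the gene lists, the rule for named loci and the alternatives, apart from array weights, were fixed before the data were examined. The rule for named loci asked for annotated functions; where there were none, it allowed 2 identifiers that rose and 2 that fell, by size of the log2 fold change among loci past the threshold whose libraries did not overlap. That second case applied. RefSeq identifiers were looked up in a table of RefSeq genes for assembly ASM5946719v1, where 3853 of 4916 LOC identifiers matched. That table gives symbols and gene classes but no descriptions, and it may describe another build, so no coordinates are given. The MSTRG names are not paired with gene names in the sources used here. For this reason 37 planned lists of gene functions matched 0 loci and gave no result. The targeted gene was not analysed here either, so the genotype labels were not checked against its expression. Whether that gene, or one beside it, is among the loci that fell is not known from the sources used here.

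The alternatives were a pseudocount of 0.1, no filter on low values, a minimum mean of 5 FPKM, rescaling by median ratios, quantile normalization, eBayes without a trend, the replicate number as a block, and leaving out each library in turn. Array weights, and the whole comparison of abundance classes, were added after the data had been seen. Count-based tests were not applied, since the values are not counts.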

Results

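Transcript levels were compared between WT and ppdnmt2 protonemata of P. patens after mannitol treatment, with 3 libraries per genotype. DNMT2 proteins are RNA methyltransferases that modify a cytosine in tRNAs, tRNA-Asp among them, and the comparison addressed how the transcriptome of the mutant differs from WT under osmotic stress. The summed FPKM was 659739, 688866 and 660508 in the WT libraries and 746107, 749097 and 803850 in the ppdnmt2 libraries, higher in all 3 ppdnmt2 libraries (exact permutation p = 0.1, the smallest possible). Between 1656 and 2808 of the 23992 loci were listed at 0 in any one library, and 1079 in all 6. Pearson's r across loci, on the log2 scale, was 0.968 to 0.981 within WT, 0.972 to 0.979 within ppdnmt2 and 0.942 to 0.978 between genotypes, where loci are not independent replicates. WT replicate 2 stood farthest from the others, with r of 0.942 to 0.969. On the first principal component, which held 43.3% of the variance, it lay at -48.8, while the other WT libraries lay at -8.1 and -4.9 and the ppdnmt2 libraries at 12.1 to 31.

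A small set of transcripts differed strongly between the single ppdnmt2 line and WT under mannitol. Of 16817 tested loci, 17 changed, of which 10 were higher and 7 lower in ppdnmt2 (limma, Benjamini-Hochberg adjusted p under 0.05). The most abundant of the named loci, MSTRG.8918, fell from 188 ± 21.3 FPKM in WT to 15.4 ± 3.29 in ppdnmt2 (mean ± SD, n = 3), which is 12.19-fold lower. MSTRG.10715 and MSTRG.13849 were close to silent in WT, at 0.131 ± 0.227 and 0.206 ± 0.18 FPKM, and rose to 6.81 ± 2.67 and 6.07 ± 1.04 FPKM in ppdnmt2 (n = 3). MSTRG.6280 went the other way, from 6.14 ± 2.56 to 0.331 ± 0.123 FPKM (n = 3).

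For MSTRG.8918 the log2 fold change was -3.54 (SE 0.17, limma adjusted p = 0.00019). For MSTRG.10715 it was 2.75 (SE 0.25, limma adjusted p = 0.0059) and for MSTRG.13849 2.55 (SE 0.17, limma adjusted p = 0.0019). MSTRG.6280 had a log2 fold change of -2.37 (SE 0.24, limma adjusted p = 0.0095). The size of the change at the 3 low loci depends on the pseudocount: with 0.1 in place of 1 the log2 fold changes were 5.27 for MSTRG.10715, 4.47 for MSTRG.13849 and -3.82 for MSTRG.6280. The call of MSTRG.10715 was lost without ppdnmt2 replicate 3 (limma adjusted p = 0.061; 0.0027 to 0.061 over 13 alternatives), and that of MSTRG.6280 without ppdnmt2 replicate 1 (0.081) or replicate 3 (0.093; 0.0019 to 0.093 over 13 alternatives). Neither locus, nor MSTRG.13849, was tested with a minimum mean of 5 FPKM.

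**Figure D1:**
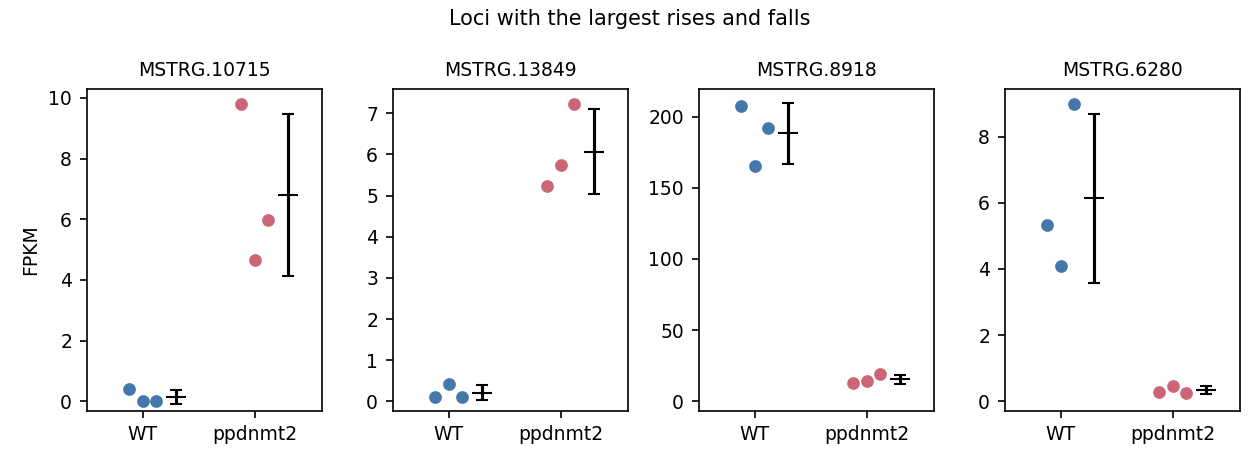
FPKM of the 4 named loci in each library; points are the 3 libraries of each genotype, and the black bar and whiskers give their mean and SD. In MSTRG.10715 and MSTRG.13849 all 3 ppdnmt2 libraries lie above the WT libraries, and in MSTRG.8918 and MSTRG.6280 all 3 lie below.

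The other 8 loci that rose had log2 fold changes of 0.93 to 1.88 (limma adjusted p from 0.00266 to 0.0484), with a median ratio of mean FPKM of 2.8. The other 5 that fell had log2 fold changes of -2.28 to -1 (limma adjusted p from 0.00446 to 0.037), with a median ratio of WT to ppdnmt2 of 3.23. Of these, 1 fell from 3.33 ± 0.634 FPKM to 0.0348 ± 0.049 (n = 3). By mean FPKM, 9 of the 10 higher and 7 of the 7 lower loci differed at least 2-fold; on the log2(FPKM + 1) scale it was 8 and 6. At all 17 loci the 3 values of one genotype lay apart from the 3 of the other; 4412 of the tested loci (26.2%) did so, where chance gives 10%. All 17 are assembled loci without a RefSeq identifier, as were 16706 of the 16817 tested loci.

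In all, 3129 loci (18.6%) had an unadjusted limma p under 0.05, 1772 higher and 1357 lower, where 841 are expected by chance. The simulated data with no changed locus gave 938. The 3129 loci include the 17 called loci, and which of the others differ cannot be told from unadjusted p-values. The split of the calls was 5 higher and 7 lower after median-ratio rescaling and 7 of each after quantile normalization. It was 6 and 5 without the filter, 5 and 5 with a minimum mean of 5 FPKM, and 5 and 6 without the variance trend. The excess of higher loci at an unadjusted p under 0.05 also turned around under quantile normalization, to 1544 higher and 1656 lower. It stayed after median-ratio rescaling, at 1892 higher and 1345 lower. The number of calls was 8 (2 higher, 6 lower) without ppdnmt2 replicate 3 and 11 without WT replicate 2. It was 54 with array weights (39 higher, 15 lower) and 108 with the replicate number as a block (77 higher, 31 lower). The replicate numbers were not taken to pair the samples, since the labels state no shared day or batch, but pairing is not excluded. The number at an unadjusted limma p under 0.05 fell to 2053 without WT replicate 2.

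**Figure D2:**
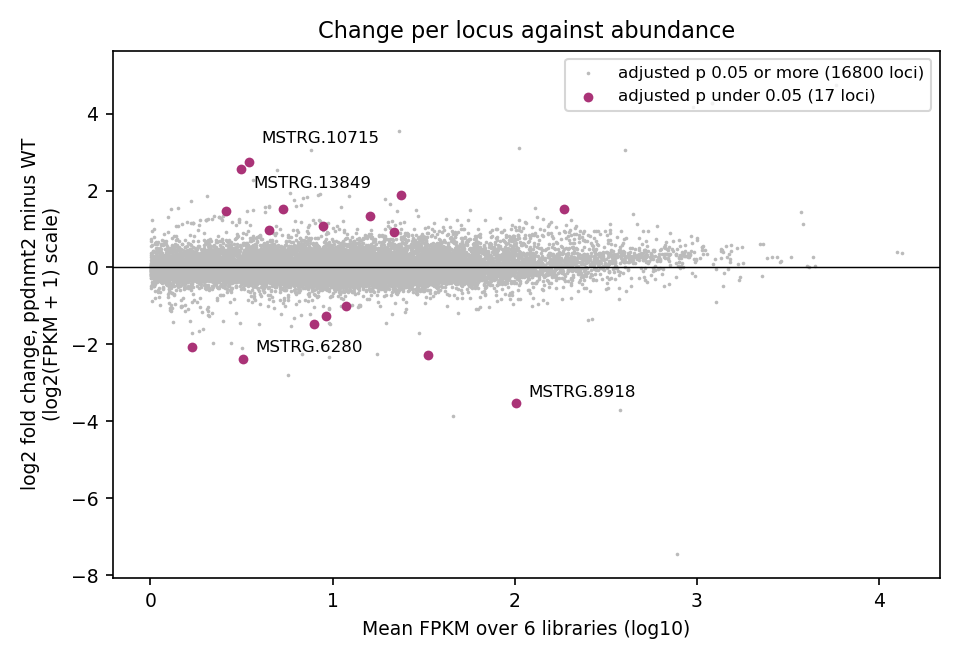
Log2 fold change of each tested locus (ppdnmt2 minus WT, on the log2(FPKM + 1) scale) against its mean FPKM over the 6 libraries on a log10 axis. Grey points are loci with an adjusted p of 0.05 or more and purple points the 17 with a lower one, of which 10 lie above and 7 below 0; several grey points with larger changes had values that differed widely between libraries of one genotype.

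Under the deposited scaling, abundant transcripts held a larger share of the FPKM in each ppdnmt2 library than in any WT library, a comparison made after the data had been seen. Among the 16705 tested loci above 0 in every library, the most abundant 10% (1670 loci with a mean of at least 74.2 FPKM) held 65.7% ± 0.3 of the FPKM in WT and 69.1% ± 0.49 in ppdnmt2 (SD, n = 3; exact permutation p = 0.1, the smallest possible). The share was 66.1%, 65.5% and 65.6% in the WT libraries and 69.6%, 68.6% and 69% in the ppdnmt2 libraries. Of these loci 1120 (67.1%) had a higher and 550 a lower mean log2 value in ppdnmt2, with a median log2 fold change of 0.13. After quantile normalization, which forces equal distributions on all libraries, 47.1% were higher and the median was -0.02. That step removes a shift between distributions whatever its source, so it cannot decide whether the shift comes from scaling. After median-ratio rescaling 69.2% were higher and the median was 0.15. An unadjusted limma p under 0.05 was reached by 445 of these loci in the higher and 64 in the lower direction. The numbers were 179 and 215 after quantile normalization, and 483 and 66 after median-ratio rescaling. Under the deposited scaling 1 was called higher and 1, MSTRG.8918, lower after adjustment. Loci with mean FPKM between 5.41 and 35.5 had median log2 fold changes of -0.06 to -0.04 in each 10% class of the tested loci.

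**Figure D3:**
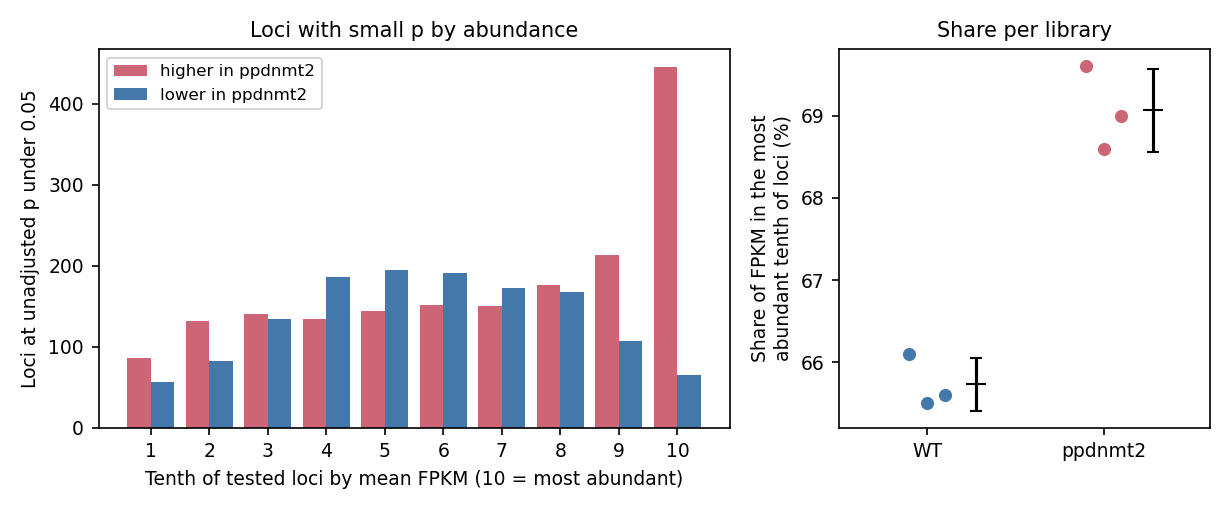
Left, number of loci with an unadjusted limma p under 0.05 in each 10% class of the tested loci by mean FPKM, higher (red) or lower (blue) in ppdnmt2. Right, share of FPKM in the most abundant 10% of tested loci above 0 everywhere, on an axis that does not start at 0; points are libraries, and the bar and whiskers give the mean and SD of 3. The top class holds 445 higher and 65 lower loci under the deposited scaling. In the most abundant 10% of tested loci above 0 everywhere, 179 were higher and 215 lower after quantile normalization, which forces equal distributions. The numbers there were 483 and 66 after median-ratio rescaling.

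Few of the loci listed under a RefSeq identifier were abundant enough to test. Annotated genes may also be among the MSTRG loci, which are not paired with gene names here. Of the loci with a RefSeq identifier, 111 passed the filter, among them 78 protein-coding genes, 8 lncRNAs, 8 snRNAs and 2 snoRNAs. In limma 0 of the 111 changed, and 0 changed when adjusted over the list alone (smallest adjusted p 0.644). With 17 calls among all 16817 tested loci, hardly any would be expected among 111. Of the 111, 3 had an unadjusted limma p under 0.05, of which 2 were higher and 1 lower in ppdnmt2. The median log2 fold change of the 111 was 0.056. All 367 annotated tRNA genes, which include 19 for tRNA-Asp with the anticodon GUC, were listed at 0 in every library, so the substrates of DNMT2 were not measured.

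SOK2 and SOK3 were the only matched RefSeq genes with a symbol of their own; both belong to the SOSEKI family, named for polarly localized proteins in plants. SOK3 (LOC112294842) stood at 0.719 ± 0.16 FPKM in WT and 0.486 ± 0.121 in ppdnmt2 (n = 3; exact permutation p = 0.1, adjusted over both genes 0.2). Its lowest WT value and its highest ppdnmt2 value were both 0.622 FPKM after rounding. SOK2 (LOC112293052) stood at 0.249 ± 0.1 and 0.173 ± 0.0605 FPKM (n = 3; exact permutation p = 0.4, adjusted 0.4). Both lie below the filter, and both were highest in WT replicate 1. That library had more signal than the others at nearly silent loci, with a median of 0.099 FPKM against 0 to 0.022. The loci were chosen for each library from the remaining libraries, which may overstate this gap.

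At 12 loci the FPKM was at least 1 in all 3 libraries of one genotype and under 0.5 in all 3 of the other, with 6 higher in ppdnmt2 and 6 in WT. The mean in the genotype with the lower values was up to 0.407 FPKM. MSTRG.10715, MSTRG.13849 and MSTRG.6280 are among them, and 4 of the 12 were called by limma, or 5 when the test was run without the filter. The 2 with a RefSeq identifier are both protein-coding and were chosen after their values were seen. LOC112284391 stood at 0.322 ± 0.128 FPKM in WT and 1.47 ± 0.462 in ppdnmt2 (n = 3), and LOC112294088 at 0.275 ± 0.137 and 1.26 ± 0.122 (n = 3). Both were below the filter, and without it neither passed limma's test (adjusted p = 0.18 and 0.093).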

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

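Array weights and the alternatives for abundance classes were chosen after seeing the data. Log2 fold changes of the 4 named loci kept their sign in all 53 combinations of locus and alternative and stayed past the threshold in 50, except MSTRG.10715 and MSTRG.6280 without 1 ppdnmt2 library. MSTRG.8918 ranged from -3.69 to -3.43 and MSTRG.13849 from 2.44 to 4.47, limma adjusted p up to 0.0027 and 0.023. The number of changed loci, 17 (10 higher, 7 lower), was 11 with no filter (6 higher), where 22913 loci were tested and 10 calls were shared, and 10 with a mean of at least 5 FPKM (5 higher), where 12086 were tested. It was 11 without the variance trend (5 higher) and 54 with array weights (39 higher, 15 lower), of which 17 were shared. Median-ratio rescaling gave 5 higher. Leaving out each library in turn gave 8 to 22 changed loci, 2 to 14 higher and 4 to 9 lower, and 2053 to 3066 at an unadjusted p under 0.05. The lowest numbers of changed and of higher loci came without ppdnmt2 replicate 3, of lower loci without ppdnmt2 replicate 1, and of unadjusted calls without WT replicate 2. Higher loci were also fewer without WT replicate 2 (5) and WT replicate 3 (6). Those fits hold fewer libraries; the cause of the other differences was not tested.

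With a replicate block, 108 loci changed (77 higher, 31 lower), which include the 17. Deviations from the genotype means correlated at -0.11, 0.14 and 0.17 for replicates 1, 2 and 3. In both genotypes replicates 2 and 3 correlated best with their own number, while replicate 1 did not. The numbers were not taken to pair the samples because the labels state no shared day or batch, but pairing is not excluded.

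The share of FPKM in the most abundant 10% of loci was 3.35 percentage points higher in ppdnmt2, and 3.02 to 3.55 leaving out 1 library. It was 2.21 for the top 100 loci and 4.46 for the top 100 of all 23992 loci, unfiltered and with loci at 0. The median log2 fold change of the most abundant 10%, 0.13, was 0.09 to 0.17 leaving out 1 library. It was 0.15 after median-ratio rescaling and -0.02 after quantile normalization. The gene lists and the targeted gene matched 0 loci, so their alternatives were not run. Absolute depth is unknown, which limits low values.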

Other observations

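Apart from the limma test of each locus, which was fixed beforehand, the tests in this part were chosen after the results they bear on had been seen. For the larger share held by the most abundant 10% of loci, a handful of extreme loci is argued against, because without the top 100 the difference was still 3.13 points and the genotypes did not overlap. Low-level signal in WT replicate 1 is argued against as well, since without that library the difference was 3.55 points. Shallower ppdnmt2 libraries cannot be told apart from genotype. In ppdnmt2 replicate 2 alone of its genotype was 1 fragment worth about as much as in the WT libraries. It had a share of 68.6%, but it is a single library, and the worth measures depth only if values were scaled to library totals. Scaling by 1 factor per library leaves shares as they are, whereas RNA quality was not tested and stays open. An effect of the genotype stays open too and was not tested.

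A pair of assembled loci with consecutive numbers changed in opposite directions. Their positions are not known here, so calling them adjacent rests on the numbers alone. The locus numbered just before MSTRG.13849 fell from 13.4 ± 1.62 FPKM in WT to 4.95 ± 0.633 in ppdnmt2 (n = 3; log2 fold change -1.27, limma adjusted p = 0.0095), while MSTRG.13849 rose. Random placements of the 17 called loci held an adjacent pair in a share of 0.014 (permutation test, 100000 placements), but the pair was noticed before the test, so chance adjacency stays open. A candidate explanation is that reads moved between 2 models of one locus, for instance by a changed transcript end or an insertion in the mutant. The summed FPKM of the pair was 13.6 ± 1.5 in WT and 11 ± 1.67 in ppdnmt2 (n = 3), a log2 ratio of -0.3 (exact permutation p = 0.2), which leaves this open because the lengths of both models are unknown.

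WT replicate 1 carried low-level signal at loci that were nearly silent elsewhere. Of 2509 loci with a mean between 0 and 0.1 FPKM in the other libraries, 83.4% were above 0 in it. The share was 44.1% to 54.9% in the other libraries, each on its own loci chosen by the same rule. Those loci can include some with signal in WT replicate 1 alone, so the gap may be overstated. If values were scaled to library totals, greater depth is argued against, since 1 fragment was worth 0.98 times its worth in WT replicate 3. Scaling of the whole library is argued against too, since the ratio of WT replicate 1 to the other libraries was 1 at loci of 2 to 5 FPKM. Background from genomic DNA or spurious transcripts may account for it: the median excess in pseudogenes was 0.89 times that in protein-coding genes, at 0.063 (40 loci) against 0.071 FPKM, with lower excesses in lncRNAs (0.046) and assembled loci (0.037). No biological explanation was tested, as WT replicate 1 shares its genotype and treatment labels with 2 libraries that lack the signal.

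There are 10 ways to split the 6 libraries into 3 and 3, too few for a share under 0.05. For the 3 counts that follow, only 1 of the 10, the real split, gave a result as large. It gave 17 changed loci where the highest other split gave 1, 3129 loci at an unadjusted limma p under 0.05 where the highest other gave 942, and 12 loci with at least 1 FPKM on one side and under 0.5 FPKM on the other where the highest other gave 3. For the most abundant 10% of loci, the real split gave a difference in share of 3.35 points and the highest other split 1.63, while the median log2 fold change of 0.13 was nearly matched by another split, at 0.12.

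Some of the highest values came from loci listed at 0 elsewhere. Of 112 tested loci at 0 in at least 1 library, 10 reached 1000 FPKM or more in some library. The summed FPKM of these 112 loci was 13455, 17959 and 9157 in the WT libraries and 34162, 41822 and 41255 in the ppdnmt2 libraries.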
